A study of Bombyx mori with 12 samples.

How the data were processed

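The series profiled BmN4 cells, a cultured germ cell line derived from the ovary of the silkworm *Bombyx mori*. Small RNAs bound to the PIWI proteins Siwi and AGO3 were recovered by immunoprecipitation and sequenced as 51 nt single-end reads, per the labels' protocols. Total RNA was sequenced as paired-end reads from directional libraries after depletion of ribosomal RNA with a human, mouse and rat kit, from cells electroporated with 500 pmol of siRNA against Siwi or against luciferase (Luc), the control. The 12 samples formed 4 groups of 3, taken from the sample titles.

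The small RNA table lists 1917863 distinct sequences of 22 to 35 nt with a value per library. The authors deposited these values as RPM, reads scaled to the library total, since each column sums to 1000000. Per the submitters' processing notes, cutadapt 4.6, Bowtie 1.3.1, SAMtools and bedtools 2.31.1 were used on these libraries; their roles, the genome build and the length filter are not given in the sources used here. The total RNA table lists 20469 genes by identifier, 1716 repeat entries by name and class, the length of each entry, and a value per library. The authors deposited these values with no unit in the header, and they were read as RPKM: each value multiplied by its entry's length was a whole multiple of the same step within a library. Trim Galore, STAR 2.7.11a and SAMtools 1.19 are named for these libraries, per the submitters' processing notes. How entries were counted, the strand setting, the treatment of reads with several hits, the annotation and the build are not given in the sources used here. Reads from near-identical repeat copies, paralogs or overlapping antisense genes may therefore have been split between entries, and repeat levels carry that uncertainty.

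Whole reads were recovered from both tables by dividing each value by the value of 1 read, and 100% of values were whole within 0.01. Small RNA libraries held 1661641 to 4462630 reads. Total RNA libraries held 14298443 to 18658221 reads in the listed entries, which made up 25.8% to 28.5% of the library totals of 54075962 to 66372594 by which the authors had scaled the RPKM values. Whether these were reads or read pairs is not stated. Small counts carry counting error, and neither assay used molecular identifiers, so floors on counts cover counting error only.

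The tests were fixed before the data were examined, with the choice between counts and normalized values left to the unit found. Because the deposited values are RPKM and RPM, the main test was limma 3.58.1 with a mean trend on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. Fold changes on that scale understate the change of low entries. For total RNA, entries at 1 RPKM or more in at least 3 libraries were tested (7530, of which 7252 genes and 278 repeats). For small RNA, sequences at 10 RPM or more in at least 3 libraries were tested (21884). No replicate block was used in the main tests. Repeat classes were taken from the names in the table and compared with all other entries by camera with a preset correlation of 0.01, adjusted over 7 sets of at least 5 members; camera with an estimated correlation and fry were run beside it. Members of each class were also counted with p-values adjusted over the list alone. edgeR 4.0.16, the quasi-likelihood test, was run on the recovered reads as an added alternative.

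The share of reads with U at position 1 (1U), the share with A at position 10 (10A) and the mean length were computed per library over reads. Groups were compared by exact two-sided permutation tests, for which 3 libraries against 3 allow no p below 0.10. Overlaps were found by sequence, without a genome: for an overlap of n nt between 5' ends on opposite strands, the 10 nt of a read that end at position n were compared with the reverse complement of the first 10 nt of all sequences in the partner library. Each library was compared with every library of the partner protein, or with the other libraries of its own protein. Values were averaged over partner libraries before the SD was taken, so the SD leaves out the spread between partner libraries. Within a protein the values of the 3 libraries share pairs and are not independent. The planned background of 5 to 9 and 11 to 15 nt was reduced to 11 to 15 nt, since overlaps under 10 nt leave too few bases for the same comparison. An expected partner level was computed from the base composition at each position of both libraries, and for reads with or without a base from the composition of those reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

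Named repeats were the 10 that rose most and up to 10 that fell most among entries past the threshold whose groups did not overlap, whose mean was at least 10 RPKM, and which carried a name and a class, with BmTE labels taken as names. Because gene identifiers have no names in the files, 2 that rose and 2 that fell were taken by the same rule. Named small RNAs were the 5 with the highest mean level in each group and the 5 with the largest change each way among those past the threshold, with groups that did not overlap and a mean level in the top 10%, which began at 46.2 RPM. Items outside these rules are marked where they appear as chosen after their values were seen.

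The table does not pair its gene identifiers with names, and 0 of them matched the RefSeq name table, so the Siwi transcript itself, the planned gene groups and the relation of piRNA level to the change on knockdown were not analysed here. The depth of the Siwi knockdown is therefore not known from these values, and the knockdown groups rest on the sample titles. Strand relative to transposons was not analysed here either, because the small RNA table gives sequences without positions. Alternatives to the pseudocount, filter, normalization, tool, length window and weighting were run, each replicate was left out in turn, and the replicate number was tried as a block; their effect is given in the closing section.

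The steps were tested on simulated data. For total RNA, limma on 7490 simulated entries recovered 52.7% of those changed 1.5-fold, 93.8% of those changed 2-fold and 100% of those changed 4-fold, and 3.70% of its calls were unchanged entries. For small RNA, with 14474 simulated sequences, the shares were 16.7%, 69.6% and 100%, with 5.66% of calls unchanged. The simulated dispersion was 0.02, and 66 or 67 sequences were changed at each fold. In the real small RNA libraries 21782 of 21884 sequences passed, so these shares need not hold there. In simulated libraries of 4000 sequences with 39.4% given a partner, the overlap search found a partner for 40.0% at 10 nt and at most 0.475% at any longer overlap. The real libraries held 335179 to 859644 distinct sequences, and their shares at 11 to 15 nt were far higher. The simulation therefore shows that the search finds planted partners, but cannot give the rate of chance matches in the real libraries. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.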

Results

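Small RNA and total RNA libraries were analysed from BmN4 cells, which express both silkworm PIWI proteins and carry an active piRNA pathway. The first comprised small RNAs bound to Siwi and small RNAs bound to AGO3, with 3 libraries each. PIWI proteins use such small RNAs, called piRNAs, as guides to recognise and cut transposon RNA. The second comprised total RNA after knockdown of Siwi or after a control siRNA against luciferase (Luc), with 3 libraries each. Small RNA libraries held 1745105, 2321772 and 1661641 reads for AGO3 and 2818059, 2900208 and 4462630 for Siwi. Total RNA libraries held 15449553, 14525491 and 14298443 reads in the listed genes and repeats for Luc knockdown, and 18658221, 14427841 and 15566777 for Siwi knockdown. The correlation of log values across entries within a group was 0.984 to 0.993 for total RNA and 0.967 to 0.991 for small RNA. No 2 replicates agreed within sampling noise: the chi-square per degree of freedom was 1.26 to 1.69 between small RNA replicates and 8.72 to 64.6 between total RNA replicates. The 2 highest values, 64.6 and 49.3, were those of Siwi knockdown replicate 2 with replicates 1 and 3.

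The first comparison asked how the piRNAs carried by Siwi differ from those carried by AGO3. Siwi-loaded piRNAs began mostly with U, whereas AGO3-loaded piRNAs mostly had A at position 10. U at position 1 was found in 83.3% ± 0.322 of Siwi reads and 35.6% ± 0.301 of AGO3 reads (SD, n = 3). A at position 10 was found in 34.7% ± 0.207 of Siwi reads and 78.0% ± 0.201 of AGO3 reads (SD, n = 3). Siwi-loaded piRNAs were also longer, with a mean of 27.9 nt ± 0.0401 against 27.1 nt ± 0.0259 (SD, n = 3). Each difference was larger than the spread between replicates, and each had p = 0.10 in an exact two-sided permutation test, the smallest value that 3 libraries against 3 allow.

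AGO3-loaded piRNAs did not favour U at the first position over A. A opened 37.6% ± 0.352 of AGO3 reads and 9.46% ± 0.188 of Siwi reads, and C opened 17.6% ± 0.161 and 3.59% ± 0.0683 (SD, n = 3). Reads with A at position 10 but no U at position 1 were 51.8% ± 0.389 of AGO3 reads and 6.28% ± 0.169 of Siwi reads. Reads with U at position 1 but no A at position 10 were 9.39% ± 0.163 of AGO3 reads and 54.8% ± 0.343 of Siwi reads. The share with both bases was close in both proteins, at 26.2% ± 0.205 for AGO3 and 28.4% ± 0.0859 for Siwi. The most frequent length was 28 nt for Siwi, with 48.6% ± 0.582 of reads, and 27 nt for AGO3, with 44.3% ± 0.229 (SD, n = 3).

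**Figure D1:**
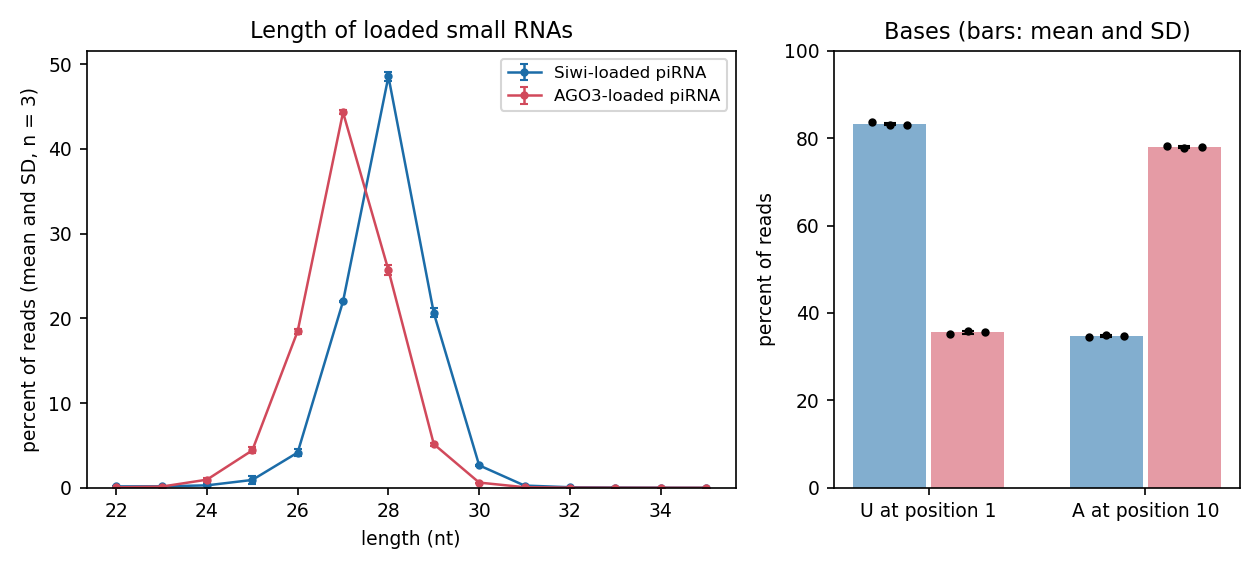
Left, percent of reads at each length in nt for Siwi-loaded and AGO3-loaded piRNAs (points, mean; bars, SD; n = 3); right, percent of reads with U at position 1 and A at position 10 (bars, mean and SD; dots, libraries). Siwi reads peak at 28 nt and AGO3 reads at 27 nt, and U at position 1 falls from 83.3% to 35.6% between them while A at position 10 goes from 34.7% to 78.0%.

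The AGO3 pool was more concentrated on few sequences. The 100 most abundant sequences of a library held 9.82% ± 0.163 of AGO3 reads and 4.28% ± 0.277 of Siwi reads (SD, n = 3). In AGO3 libraries 5356 ± 146 sequences made up 50% of reads, and in Siwi libraries 17578 ± 1109 did (SD, n = 3; exact permutation p = 0.10 for each measure).

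Nearly all abundant sequences differed in level between the proteins. Of 21884 sequences tested, 21782 passed the threshold, 11771 of them higher with Siwi and 10011 higher with AGO3. The sequences higher with Siwi made up 43.8% of Siwi reads and 3.22% of AGO3 reads. Of these, 90.5% began with U, 34.3% had A at position 10, and the mean length was 28.03 nt. The sequences higher with AGO3 made up 57.6% of AGO3 reads and 0.641% of Siwi reads. Of these, 31.3% began with U, 86.3% had A at position 10, and the mean length was 27.0 nt. The odds ratio between the called sets was 20.97 for U at position 1 and 12.1 for A at position 10. The groups did not overlap for 99.6% of sequences tested, where chance gives 10%. The filter let a sequence enter through the protein where it was high, which favours sequences whose groups lie apart. Of 5' ends, taken as the first 22 nt, 1465 were at 10 RPM or more with both proteins, 358 of them within 2-fold. Over 10 times richer with 1 protein were 10042 ends for Siwi and 9218 for AGO3. The edgeR test on recovered reads with TMM scaling called 17487 higher with Siwi and 18840 higher with AGO3, and the same test without TMM called 34218 and 16678. Of the 21782 limma calls, 18111 were shared in direction with TMM and 21776 without it.

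The most abundant Siwi-loaded piRNA was TATCGGAACGAACGGTTCGACAAGTAGT, at 1620 ± 50.1 RPM with Siwi and 163 ± 16.8 RPM with AGO3 (SD, n = 3). AACTCAAGACACAAGATCGCGACGGCAGC followed with 1297 ± 283 RPM against 22.1 ± 1.79 RPM, and it was the sole member of the Siwi top 5 that did not begin with U. TACTTTTCAAAGGACTTATGGGCCACCC had 1011 ± 93.6 RPM with Siwi, TATCGAAGAAGAGGGCTCCTGTCGGAAT 1003 ± 94.4 RPM and TAAACGGATGCGATGACGATCGGCTGGT 993 ± 137 RPM. The most abundant AGO3-loaded piRNA was CATCCGTTTATCTCCCCCTGACAAAAAA, at 3490 ± 98.2 RPM with AGO3 and 29.2 ± 5.32 RPM with Siwi (SD, n = 3). CTGGAACTTCCCGCACCAATAGAACAGC had 3353 ± 254 RPM with AGO3, AACTATAATAATGAGCACAGTTTCTGA 2704 ± 46.6 RPM, TCCCACAAGATTGTCCCGAATTCAAGA 2670 ± 234 RPM and ATTATGTCAAAAAACACTCAAAGAATGC 2328 ± 123 RPM. These 10 sequences passed the limma test in the direction of the protein they ranked under.

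Among abundant sequences, the largest shift towards Siwi was that of TAGTCGTGTACTATTGACCTTAGTTCAAAC, with 296.6 ± 1.12 RPM against 1.10 ± 1.54 RPM, a log2 fold change of 7.39 ± 0.44 (SE). TAACTATACGCCACTTTTGTTGGCCTGAT, TAATAGTCATAACATGAACGCAGCAGCC, TTACAAATGAAAATATATGTTGAACATGC and TAAGAATTTTATTCGCGGATACGAAGTC followed with 231.8, 268, 337 and 385 RPM with Siwi, and all 5 began with U. The largest shift towards AGO3 was that of AACATCAGATTTAAAGGATACTTTGTC, with 964 ± 50.9 RPM against 0.687 ± 0.340 RPM with Siwi, where 7 reads were seen over the 3 libraries. Its log2 fold change of Siwi over AGO3 was -9.18 ± 0.17 (SE). AGAGGAATTTAGAAATAGAAAAAGAGT had 813 ± 49.9 RPM with AGO3, TTCATCGCTACGTCGACCGCTACGAGA 2293 ± 158 RPM, TGACAGTGATAAAATGTATGTAAATTC 2059 ± 120 RPM and CGAGACGATGAATTCATTTACAAAAAC 817 ± 13.7 RPM. All 5 of these were 27 nt long.

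Reads of the 2 proteins were then compared for the 10 nt overlap between 5' ends that the ping-pong cycle leaves, in which each protein cuts the RNA from which the other's guide is made. Overlaps of 10 to 20 nt were searched, and within these Siwi reads and AGO3 reads overlapped most often by 10 nt. A partner in the AGO3 libraries was found at 10 nt for 78.5% ± 0.317 of Siwi reads, against a mean of 33.7% ± 0.355 at 11 to 15 nt (SD, n = 3). A partner in the Siwi libraries was found at 10 nt for 90.8% ± 0.0820 of AGO3 reads, against 52.8% ± 0.142 (SD, n = 3). Shares within a protein rose at 10 nt too, with 73.8% ± 1.38 against 30.9% ± 1.31 between AGO3 libraries and 68.0% ± 2.37 against 45.5% ± 2.23 between Siwi libraries (SD, n = 3). For AGO3 reads the excess was 42.97 points with AGO3 and 38.0 with Siwi partners, but the order turned once matches were restricted: 11.1 and 41.3 points among sequences at 10 RPM or more, and 14.5 and 47.4 with partners of at least 10 reads. Within the overlaps searched, that of 10 nt held the highest share in all 3 libraries of each of the 4 combinations of read and partner protein.

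Weighted by reads, partner levels were higher between the proteins than within one. Summed over partners, the level per read at 10 nt was 56.9 RPM between Siwi and AGO3, 20.9 times that at 11 to 15 nt for Siwi reads and 17.8 times for AGO3 reads. Between AGO3 libraries it was 11.5 ± 0.130 RPM, 6.89 times its background, and between Siwi libraries 6.33 ± 0.0261 RPM, 2.92 times its background (SD, n = 3). Over distinct sequences this contrast was kept in part. A Siwi sequence had a mean of 2.56 partner sequences in AGO3 and 2.63 in Siwi libraries, 2.68 and 1.55 times the background. An AGO3 sequence had 4.91 in Siwi and 2.14 in AGO3 libraries, 2.45 and 2.55 times the background. Base composition alone, with the excess of U at position 1 and A at position 10, gave an expected level of 5.08 RPM at 10 nt between the proteins, so the observed level was 11.2 times the expected one. The same ratio was 4.82 between AGO3 libraries and 2.23 between Siwi libraries, and at 11 to 15 nt it was 1.02 to 1.46 in the 4 combinations.

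**Figure D2:**
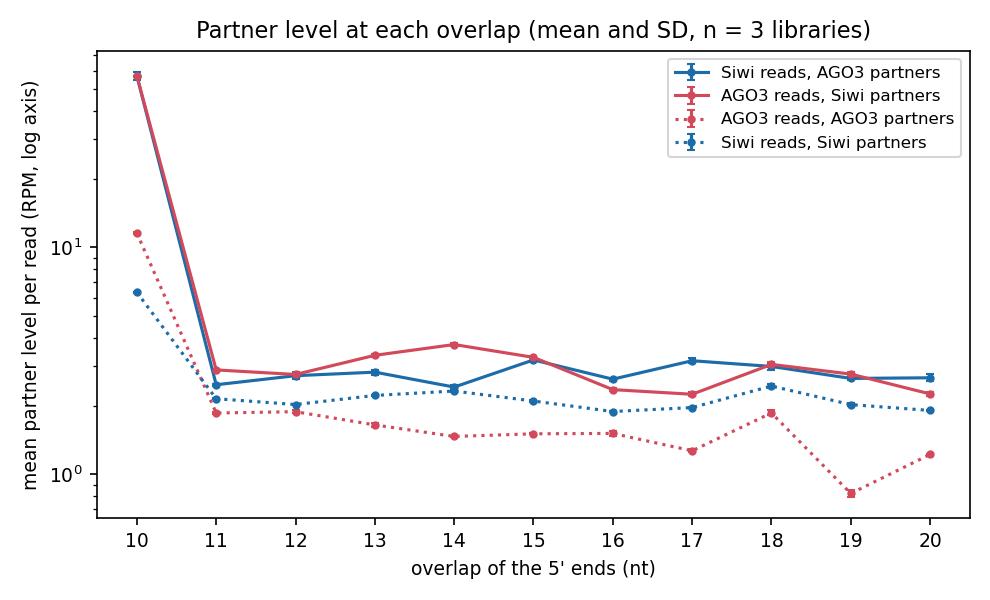
Mean summed level of partner sequences per read, in RPM on a log axis, at each overlap of 5' ends from 10 to 20 nt, for the 4 combinations of read and partner protein (points, mean; bars, SD; n = 3 libraries). At 10 nt the level is 56.9 RPM between Siwi and AGO3, 11.5 RPM within AGO3 and 6.33 RPM within Siwi.

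Reads were split by their own bases. Counting partners with at least 10 reads, 62.1% ± 0.191 of AGO3 reads with A at position 10 had a Siwi partner, against 31.3% ± 0.384 of those without it (SD, n = 3). Likewise 33.99% ± 0.260 of Siwi reads with U at position 1 had an AGO3 partner, against 12.3% ± 0.0982 of those without it (SD, n = 3). The converse splits differed less. An AGO3 partner was found for 32.7% ± 0.220 of Siwi reads with A at position 10 and 29.1% ± 0.348 of those without it, and a Siwi partner for 50.4% ± 0.449 of AGO3 reads with U at position 1 and 58.0% ± 0.150 of those without it (SD, n = 3). Position 10 of a read pairs with position 1 of its partner, so such splits follow base composition in part. The partner level of AGO3 reads was 67.2 RPM with A at position 10, 10.4 times that expected from composition, and 20.3 RPM without it, 44.7 times that expected. For Siwi reads it was 62.97 RPM with U at position 1 and 26.7 RPM without it, 10.4 and 45.5 times that expected. Reads without the base thus had a lower level but a higher ratio to composition. Partners were matched on 10 nt, so a share of matches arises by chance and grows with depth.

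The second comparison asked how total RNA changed when Siwi was depleted, with transposon RNA as its main interest. Of 278 repeats tested, 89 rose, 8 fell and 181 did not pass the limma test, while of 7252 genes 525 rose and 1370 fell. The share that rose was 32.01% of repeats and 7.24% of genes, an odds ratio of 6.03 (Fisher's exact p = 6.7e-32, across entries, which are not independent). The median log2 fold change was 0.27 for repeats and -0.12 for genes, a difference of 0.39. The size of this difference depended on the settings of the limma test. It was 0.53 with a pseudocount of 0.1 and 0.19 with a pseudocount of 5. Among entries at 10 RPKM or more it was 0.69, and with no filter beyond a value above 0 in 1 library it was 0.08. In edgeR on recovered reads, which used another scale and kept more entries, the gene median was 0.01 with TMM and -0.09 without it, and the difference 0.50 and 0.49.

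Each repeat class with at least 5 members tested had a median above that of genes. The DIRS class was smaller and was not tested as a set. Its entries BmTE_RM6-1297, BmTE_RM6-1298 and BmTE_RM6-2105 rose, and were chosen after their values were seen. Of 65 LTR retrotransposons, 29 rose and 3 fell, with a median log2 fold change of 0.30 (0.42 above genes). Of 46 DNA transposons, 16 rose and 1 fell, with a median of 0.33. Of 41 LINE retrotransposons, 10 rose and 1 fell, with a median of 0.18. Of 111 unclassified repeats, 27 rose and 2 fell, with a median of 0.23. Of 7 SINE entries, Nagisa and Amanoya rose and Bm1 fell, and of 5 Helitrons, Helitron-1_BM and BmTE_RM6-4364 rose. Nagisa, Amanoya and both Helitrons were chosen after their values were seen. Adjusted over the list alone, 32 LTR entries rose and 3 fell, 22 and 1 of DNA, 10 and 1 of LINE, 27 and 2 of unclassified, 3 and 1 of SINE, 3 and 0 of Helitron entries.

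Camera with the preset correlation placed every class of at least 5 members above the other entries. The camera adjusted p was 4.5e-15 for LTR, 1.1e-13 for DNA, 1.9e-06 for LINE, 4.0e-12 for unclassified, 0.0073 for Helitron and 0.0495 for SINE entries. None of these calls held with an estimated correlation, where the adjusted p was 0.168 for LTR, DNA and Helitron, 0.189 for LINE, 0.224 for unclassified, 0.398 for SINE and 0.168 for all repeats together. Fry asks whether the members of a set move one way on balance. Its adjusted p was 0.014 for LTR, 0.035 for DNA, 0.037 for LINE, Helitron and all repeats, 0.159 for unclassified and 0.312 for SINE entries. The unadjusted fry p moved with the setting. Without Luc knockdown replicate 1 it was 0.014 for LTR, 0.038 for DNA, 0.073 for LINE, 0.092 for Helitron and 0.090 for all repeats. With the replicate number as a block these were 0.017, 0.058, 0.053, 0.153 and 0.086. With quantile normalization the fry p was 3.7e-05 to 0.0069 over the classes and all repeats.

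**Figure D3:**
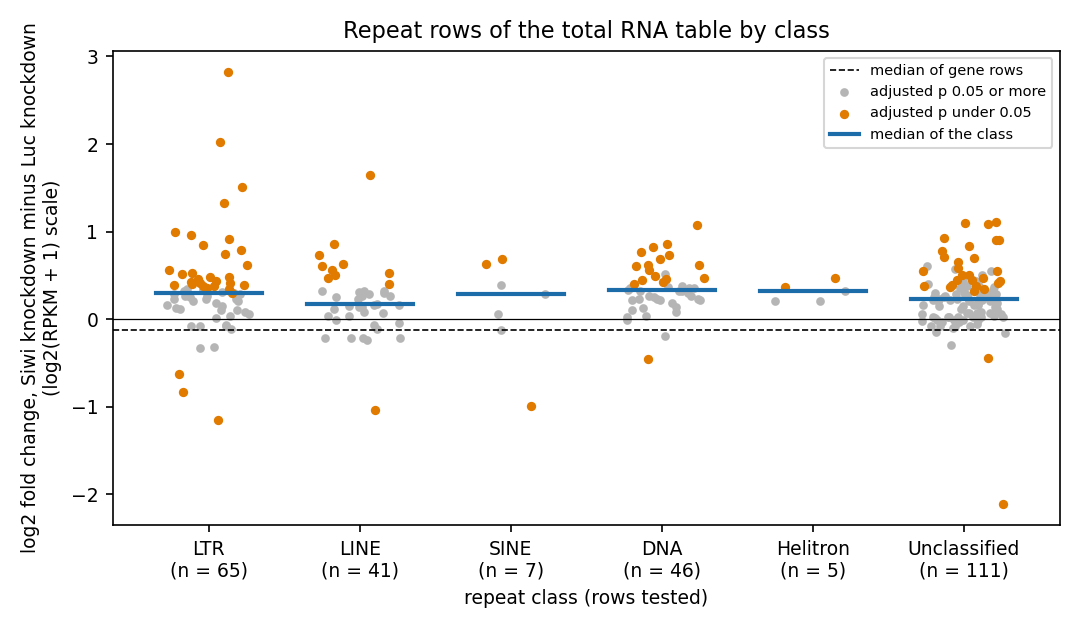
Log2 fold change of each tested repeat, Siwi knockdown minus Luc knockdown, by class (points, repeats; orange, adjusted p under 0.05; blue bars, class medians; dashed line, median of genes at -0.12). Class medians lie between 0.18 for LINE and 0.33 for DNA entries, and the DIRS entries are not shown.

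Of the 5 largest rises, 4 were in Gypsy elements, which are LTR retrotransposons, and the third was in BmTE_RM1-504, a LINE. BmTE_RM6-6875 went from 16.2 ± 1.61 RPKM in Luc knockdown to 120.1 ± 7.26 RPKM in Siwi knockdown (SD, n = 3), a log2 fold change of 2.82 ± 0.14 (SE) with a limma adjusted p of 7.4e-10. BmTE_RM6-4418, BmTE_RM6-2827 and BmTE_RM6-9737, also Gypsy, had log2 fold changes of 2.02 ± 0.14, 1.51 ± 0.13 and 1.32 ± 0.15 (SE). Kabuki, a further Gypsy element, rose from 51.0 ± 2.20 to 102.9 ± 7.85 RPKM (SD, n = 3). Among the other LTR elements, FUI rose from 125 ± 14.6 to 225 ± 25.2 RPKM and Inoki, of the Pao family, from 7.43 ± 0.251 to 13.6 ± 1.49 RPKM.

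Members of the LINE and DNA classes completed the 10. BmTE_RM1-504, of the CR1 family, rose from 10.7 ± 0.919 to 35.9 ± 3.85 RPKM, a log2 fold change of 1.65 ± 0.14 (SE). R2Bm, which inserts into ribosomal RNA genes, rose from 803 ± 51.4 to 1466 ± 192 RPKM, a log2 fold change of 0.86 ± 0.15 (SE) with a limma adjusted p of 5.9e-04. Ribosomal RNA was depleted with a human, mouse and rat kit, and how much silkworm ribosomal RNA each library kept was not tested. BmTE_RM1-432, a DNA transposon, rose from 21.7 ± 3.29 to 40.2 ± 6.41 RPKM. In all 10 the 3 Siwi knockdown values lay above the 3 Luc knockdown values, which the naming rule required. These 10 were among 26 repeats that rose and met that rule.

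Some repeats fell, and 5 met the rule. Pao, an LTR element, fell from 41.7 ± 5.29 to 18.2 ± 0.271 RPKM, a log2 fold change of -1.15 ± 0.14 (SE; limma adjusted p = 1.8e-05). L1Bm, a LINE, fell from 39.8 ± 4.48 to 18.8 ± 0.302 RPKM. Bm1, the abundant silkworm SINE, fell from 1636 ± 73.2 to 833 ± 170 RPKM, a log2 fold change of -0.99 ± 0.17 (SE), which was -0.42 with quantile normalization. LTR-2_BM-I had -0.62 ± 0.18 (SE; limma adjusted p = 0.020) and ISL2EU-1_BM, a DNA element, -0.46 ± 0.15 (SE; limma adjusted p = 0.035), and with quantile normalization neither passed (limma adjusted p = 0.062 and 0.135). Chosen after their values were seen, the remaining 3 were BmTE_RM1-295, unclassified, with -2.11, Rikishi_Kabuki_type, a Gypsy element, with -0.83, and BmTE_RM1-246, unclassified, with -0.44. BmTE_RM1-246 did not pass in edgeR with TMM (edgeR adjusted p = 0.078).

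**Figure D4:**
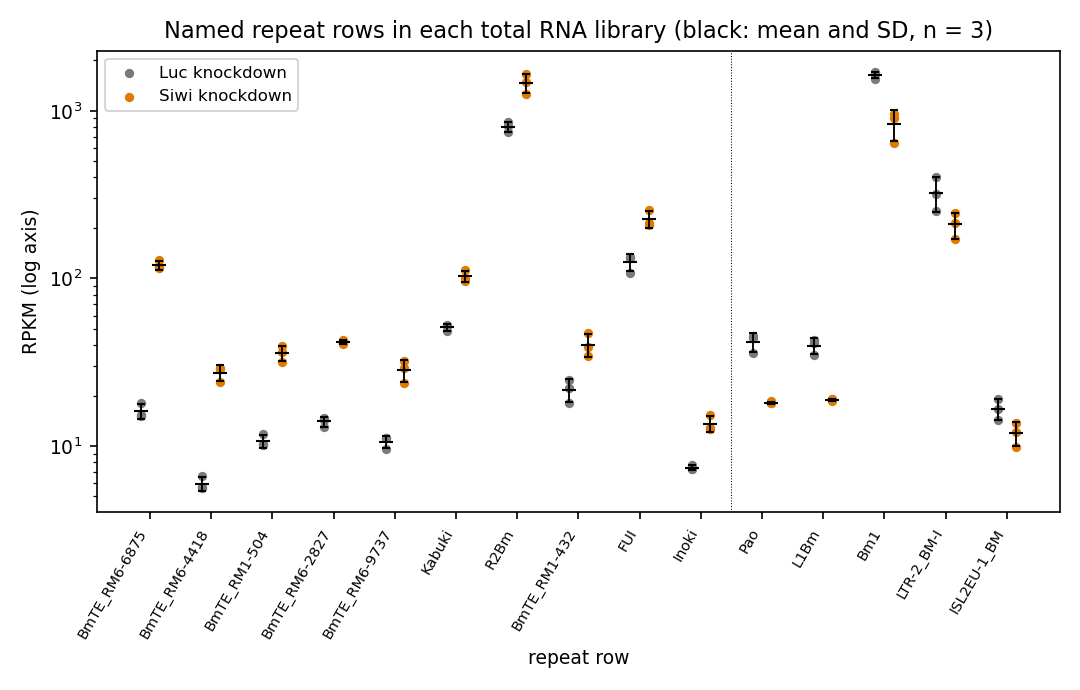
RPKM on a log axis of the 10 named repeats that rose and the 5 that fell, in each total RNA library (dots; black marks, mean and SD, n = 3). BmTE_RM6-6875 goes from a mean of 16.2 to 120.1 RPKM, R2Bm from 803 to 1466 RPKM and Bm1 from 1636 to 833 RPKM.

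Among genes, the files do not pair identifiers with names, so 2 that rose and 2 that fell are given by identifier. BMgn003210 rose from 89.5 ± 6.28 to 947 ± 65.4 RPKM (SD, n = 3), a log2 fold change of 3.39 ± 0.15 (SE), and KWMTBOMO15791.mrna1 from 6.54 ± 0.604 to 40.1 ± 2.37 RPKM. KWMTBOMO07274.mrna1 fell from 44.6 ± 2.39 to 4.12 ± 0.523 RPKM, a log2 fold change of -3.16 ± 0.14 (SE), and BMgn014584 from 145 ± 18.1 to 33.2 ± 1.71 RPKM. At 2-fold or more on the log2(value + 1) scale, 85 genes rose and 65 fell, and 9 repeats rose and 3 fell. That scale understates changes, and Kabuki, at 2.02-fold in mean RPKM, was not counted. Groups did not overlap for 41.6% of all entries tested, where chance gives 10%.

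The balance of gene calls depended on scaling, on the filter and on the libraries used. With the deposited scaling, 9.07% of genes called in the limma test rose at 10 RPKM or more. With no filter beyond a value above 0 in 1 library, 46.0% rose. Leaving out each library gave 16.8%, without Siwi knockdown replicate 2, to 38.0%, without Siwi knockdown replicate 3. Of the genes called, 27.7% rose in the main limma test with the deposited scaling and 46.8% with quantile normalization. In the edgeR test 50.9% rose with TMM and 38.4% without it. The share was 62.4% once the most abundant entry was left out and libraries were rescaled to their other listed reads. That rescaling also replaced the library totals, of which unlisted reads were the larger part, and these changes were not separated. Of the 89 repeats that rose, 85 also rose in the edgeR test with TMM, which called 177 repeats higher and 9 lower. Without Luc knockdown replicate 1 the limma test called 1096 genes and 57 repeats, and without Siwi knockdown replicate 3 it called 1123 genes and 73 repeats.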

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

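The edgeR tests, the test without the most abundant entry, the partners with at least 10 reads, and the class tests with an estimated correlation were chosen after the data were seen. The other alternatives, fry among them, were planned. The balance of calls turned with the setting. In the limma test 614 total RNA entries rose and 1378 fell, against 1620 and 1401 in edgeR with TMM. They were 1428 and 773 without the most abundant entry, with libraries rescaled to their other listed reads. At 10 RPKM or more they were 112 and 768, and without Siwi knockdown replicate 2 they were 508 and 2172. With quantile normalization they were 998 and 997. For small RNAs 11771 were higher with Siwi and 10011 with AGO3, against 1818 and 2250 at 50 RPM or more. In edgeR they were 17487 and 18840 with TMM, and 34218 and 16678 without it. The TMM factors, which move all sequences of a library alike, were 2.24 to 2.66 for Siwi and 0.390 to 0.404 for AGO3 libraries. The count of changed total RNA entries, 1992, was 880 at 10 RPKM or more and 3021 in edgeR with TMM. It was 162 with a minimum of 2-fold on the log2(value + 1) scale. Fewer or more entries entered 2 of these tests by construction. Leaving out each library gave 1153 to 2680, the lowest without Luc knockdown replicate 1, followed by 1196 without Siwi knockdown replicate 3. The count of changed repeats, 97, was 42 at 10 RPKM or more, 186 in edgeR with TMM and 163 without the most abundant entry; leaving out each library gave 57, without Luc knockdown replicate 1, to 130. The count of small RNAs, 21782, was 4068 at 50 RPM or more, 59829 at 3 RPM or more, 36327 in edgeR with TMM and 50896 without TMM, and 21750 to 21769 with a library left out. For these counts the cause of a difference between tools was not tested.

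Composition kept its direction while its size moved. Over distinct sequences, without the 100 most abundant sequences, and among sequences at 10 RPM or more, the difference in U at position 1 (Siwi minus AGO3) was 25.3, 46.4 and 59.5 percentage points, and that in A at position 10 was -32.9, -44.4 and -46.2. The length difference was 0.635 nt over distinct sequences and 0.952 nt at 10 RPM or more. With a library left out the ranges were 47.5 to 47.8, -43.4 to -43.2 and 0.826 to 0.862 nt. The excess of partners at 10 nt over 11 to 15 nt was 25.4 points for Siwi reads and 25.2 for AGO3 reads over distinct sequences, where it was 25.5 between AGO3 libraries and 11.8 between Siwi libraries, and over reads it was 42.97 and 22.5 within the proteins. It was 32.7 and 41.3 at 10 RPM or more, where it was 11.1 between AGO3 and 4.53 between Siwi libraries. With partners of at least 10 reads it was 27.2 and 47.4, against 14.5 and 9.02; leaving out a library gave 44.4 to 45.2 and 37.2 to 39.5. The cause was not tested.

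The 19 named repeats and gene identifiers kept direction and call in 272 of 285 settings, and LTR-2_BM-I and ISL2EU-1_BM lost their call in the other 13. The 20 named sequences kept theirs in all 280. Class tests kept their call in 69 of 84 settings and lost it in 15, of which 7 were for SINE entries; each class lost it with the estimated correlation.

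Replicate numbers did not pair the samples: deviations of libraries with the same number correlated at -0.27 to 0.36 for total RNA and -0.003 to 0.01 for small RNA, and 2 of 6 libraries correlated best with their own number in each. With the number as a block, 1864 entries, 91 repeats and 21774 small RNAs passed. DESeq2 and limma-voom were planned for count tables and were not run on the recovered reads; library size alone was run in edgeR, with 2650 total RNA entries and 50896 small RNAs. Not run was any test of the Siwi transcript, gene groups, strand and the relation of piRNA level to knockdown. Changes of 1.5-fold lay near the limit of detection in simulated data.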

Other observations

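The tests of scaling, of the most abundant entry, of entry length, of the origin of 5' U reads and of repeat families were chosen after the results were seen. The splits of the libraries and the read length test were planned.

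By family, 17 of 33 Gypsy elements rose and 1 fell, and 8 of 19 Pao elements rose and 1 fell in the limma test. Fisher's exact test of the shares that rose did not pass the threshold (p = 0.57), and edgeR with TMM called 25 of 58 Gypsy and 25 of 32 Pao elements higher. The 6 LTR entries without a family lay lower, with 2 that rose and 1 that fell. Their median log2 fold change was -0.19, which is -0.07 from that of genes. Of 6 LINE entries of the L2-Daphne family, 5 rose (Benkei, BmTE_RM1-217, BmTE_RM5-279, Sake2_BM and Takuya), and of 11 TcMar DNA transposons 5 rose (MAR1_BM, Mariner-2_BM, Mariner-7_BM, BmTE_RM1-364 and BmTE_RM6-8176); these were chosen after their values were seen. Of 12 R1 and 6 LINE/I elements, 0 passed the limma test in either direction; 3 and 2 had an unadjusted p under 0.05, and edgeR with TMM called 6 of 18 R1 and 3 of 9 LINE/I elements higher.

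The most abundant entry, BmTE_RM5-571, an unclassified repeat of 9536 nt chosen after its values were seen, went from 7507 ± 674 to 12357 ± 2439 RPKM (SD, n = 3; log2 fold change 0.70, limma adjusted p = 0.0048). It took 27.7% ± 2.46 of reads in the listed entries after Luc knockdown and 42.3% ± 7.08 after Siwi knockdown (SD, n = 3; exact permutation p = 0.10). Siwi knockdown replicate 2 had 34.1%, the lowest of its group. R2Bm was also lowest there within that group, at 1267 RPKM against 1650 and 1482 RPKM in replicates 1 and 3. With quantile normalization the fold change of BmTE_RM5-571 was 0, which holds by construction for the top-ranked entry. Of the remaining reads, repeats took 5.95% ± 0.367 after Luc and 9.64% ± 0.868 after Siwi knockdown, and LTR elements 1.56% ± 0.0527 and 2.64% ± 0.0908 (SD, n = 3). R2Bm alone went from 1.88% ± 0.172 to 4.06% ± 0.829, SINE entries from 0.381% ± 0.0276 to 0.274% ± 0.0486, and the other unclassified repeats from 0.925% ± 0.0591 to 0.923% ± 0.0587 (SD, n = 3; exact permutation p = 0.90 for the last).

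The median of repeats was higher after Siwi knockdown, although 181 of 278 did not pass the limma test and 8 fell. The camera call for all repeats was lost with an estimated correlation (adjusted p = 0.168), while fry gave an adjusted p of 0.037. A factor per library moves repeats and genes alike, so scaling leaves the distance of repeats from genes as it is. In edgeR that distance was 0.49 with library totals and 0.50 with TMM. The median log2 fold change of repeats was 0.40 with library totals and 0.50 with TMM. TMM set the gene median to 0.01, so the level with TMM follows from the distance and cannot decide whether scaling raised the repeats. The most abundant entry is argued against as a cause through scaling, because its share of listed reads rose by 14.6 percentage points without overlap of the groups, and a rise lowers the scaled values of other entries. A change in the total RNA of the cells stays open, since these values are relative. Reads shared between repeat copies and the treatment of reads with several hits stay open, since the sources used here do not give them, as does an effect of Siwi depletion itself, which was not tested apart from these.

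Abundant genes lay below others after Siwi knockdown. With TMM the median log2 fold change was -0.46 for the 100 most abundant genes, -0.32 for the next 400, -0.22 for the next 500, -0.15 for the next 1000 and 0.03 for ranks below 4000, and 75 of the top 100 fell while 3 rose in the limma test. The median of the top 100 was -0.57 in the limma test and -0.46 with TMM, where the quartiles were -0.59 and -0.34. TMM set the gene median to 0.01, and the tool changed as well, so this move cannot decide whether scaling lowered abundant genes. The distance of the top 100 from the ranks below 4000, which scaling leaves as it is, was taken relative to the Luc libraries. It was -0.69, -0.47 and -0.40 in the Siwi knockdown libraries. In the Luc libraries, which are their own reference, it was 0.09, -0.001 and -0.12 and shows only their spread. Scaling to the library total is thus argued against as the whole cause of this distance. Entry length alone is argued against, since within 1000 to 2500 bases the top 500 lay -0.26 from the ranks below 4000. Quantile normalization removes such a trend by construction, with a median of -0.04 for the top 100 and 0.05 for the top 500 of 1000 to 2500 bases. A shift in RNA composition, RNA quality or the response of the cells may each underlie the -0.46 seen with TMM and were not tested.

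Some 5' U reads in the AGO3 libraries might be Siwi piRNAs carried over in the immunoprecipitation. This is argued against as the main source, since 72.8% ± 0.768 of these reads came from sequences more abundant in the AGO3 libraries (SD, n = 3) and 20.1% ± 0.600 from sequences more abundant with Siwi. Over all AGO3 reads these shares were 83.8% and 8.84%. The 5' U reads thus came from Siwi-richer sequences more often than AGO3 reads at large, and carry-over of a part stays open. For 5' ends at 10 RPM or more with Siwi and over 10 times richer there than with AGO3, which held 1.80% of AGO3 reads, reads were shorter in the AGO3 libraries by 0.244 nt ± 0.0146 (SD, n = 3). That lies between the bounds set in advance for carry-over, under 0.1 nt, and for AGO3's own reads, over 0.4 nt, so a mixture stays open for these ends. The 358 ends at 10 RPM or more in both proteins and within 2-fold of each other, with 0.972% of AGO3 reads, were shorter with AGO3 by 0.814 nt ± 0.00964 (SD, n = 3).

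The 6 libraries of each assay, in groups of 3, give 10 splits, too few for a share under 0.05. The real split gave 1992 changed total RNA entries and the highest other split 1; for repeats these were 97 and 0, and for small RNAs 21782 and 0. In each case 1 of the 10 splits, the real one, gave as many. Every other split mixed the real groups, which turns their difference into spread within a group. Its count is therefore not a rate of chance calls.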
